A study of Mus musculus with 6 samples.

How the data were processed

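Neutrophils were purified by flow cytometry as Ly6G-positive cells from perfused lungs that had been minced and digested with liberase, per the labels' protocols. The 3 mutant mice carried the S100A8-Cre transgene and loxP-flanked Tgfbr2, and the 3 wt mice were Cre-negative littermates with loxP-flanked Tgfbr2. Per the labels' protocols, cDNA was made from 2 ng of total RNA with ERCC spike-in RNA by SMART-Seq v2, which copies polyadenylated RNA over its full length and does not mark strand, and libraries were made with Nextera XT and sequenced as paired ends of 151 cycles. The amplification adds noise at low expression, and read counts without molecular identifiers include PCR copies, so that counting intervals and floors cover counting error only.

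The authors deposited one table of whole-number read counts per gene, raw and not normalized. Per the submitters' processing notes STAR, featureCounts and the mouse build GRCm38 were used, while versions, the annotation release and the strand setting are not given in the sources used here. Per the file headers each gene has the positions of its exons and their summed length, so a count pools every exon of a gene. The table has 55487 genes, of which 29379 had no count in any library. Symbols came from GENCODE M21, the annotation of GRCm38: 55094 identifiers matched exactly, 300 matched without their version and 93 kept no symbol. Library totals were 35906780, 30403494 and 31560629 counts for mutant replicates 1 to 3 and 30577737, 30423365 and 32132330 for wt replicates 1 to 3. Replicate numbers follow accession order, in which mutant and wt libraries alternate, so an equal number does not by itself mark a pair. Whether mutant and wt libraries were paired by litter or by processing is not given in the sources used here. All tests treated the libraries as unpaired, and a pairing was not tested. The 10 most abundant genes took 9.74% to 10.7% of the counts and mitochondrial genes 0.223% to 0.334%. The table was searched for spike-in rows and held 0, so the planned spike-in share and spike-in scaling were not analysed here.

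Genes were kept by edgeR's filterByExpr with its default minimum count of 10, which left 15774 genes and 99.9% of the counts of each library. Libraries were scaled by TMM (factors 0.972 to 1.03), and mutants were compared with wt by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with Benjamini-Hochberg adjustment at 5% over all tested genes. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM values are TMM-scaled. The median biological coefficient of variation was 0.159 for genes with a mean of at least 10 CPM.

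Before the data were examined, 41 lists were fixed: 27 gene lists and 14 lists of cell type markers. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 38 lists with at least 5 tested members, and again with an estimated correlation and with fry. Several lists share members. Counts called adjusted over the list alone apply the adjustment to the members of that list. Marker lists were also summed in CPM over each library and compared by a two-sided exact permutation test over the 20 assignments of 3 of the 6 libraries. The genes named are Tgfbr2; the 12 genes with the smallest p in each direction among those with an established symbol, non-overlapping groups and a mean CPM of at least 5, filled up with genes that do not pass; and of each list up to 4 called members or, with no called member, the 2 with the smallest p. Other genes named were chosen after their values were seen: Smad7, Skil, Il1b, Tnf, H2-K1, Gsn, Scgb1a1, Foxj1, Jchain, Igkc, Iglc2, Igha, members named only as passing adjusted over a list alone, and the further genes of the closing section. Single-gene values of some genes that this rule or the plotted region around Ap1s1 would include are not reported here.

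The test was checked on simulated counts for this comparison over 15774 genes with 200 genes changed by known folds. It recovered 10% of the genes changed 1.5-fold, 32% of those changed 2-fold, 66% of those changed 4-fold and 74% of those changed 8-fold, and, among genes with a mean of at least 10 CPM, 22.7%, 78.9%, 100% and 100%. It called 6 of 15574 unchanged genes there and 0 when no gene was changed. DESeq2 (1.42.0) called 39 of 15574 and 11 in the same simulations, and limma-voom 3 and 0. A simulated list shifted by 1.3-fold was found with a camera adjusted p of 1.3e-09 and 0 other lists were called. Simulated genes were drawn independently of each other, whereas the correlation estimated for the ribosomal protein list was 0.58. The check therefore cannot show how often the preset correlation calls lists whose members vary together. Alternatives were DESeq2's size factors, library totals alone, DESeq2's Wald test, limma-voom with and without quality weights, edgeR's robust option, no filter on low counts, a mean of at least 10 CPM, an added log2 fold change of at least 1, and leaving out each library in turn. An edgeR fit with legacy = FALSE was added after seeing the data.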

Results

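The data are RNA-seq profiles of neutrophils sorted from mouse lung by the surface protein Ly6G. The comparison is between 3 libraries from mice in which Cre recombinase, driven by the S100A8 (Mrp8) promoter, deletes loxP-flanked Tgfbr2 in neutrophils (mutant) and 3 libraries from littermates with the same loxP-flanked alleles but no Cre (wt). Tgfbr2 encodes the type II receptor for TGF-beta, a cytokine that restrains many immune cells. The design asks what lung neutrophils transcribe when this receptor gene is targeted for deletion. How complete the deletion was in these cells was not analysed here. The count table held 55487 genes, and library totals ran from 30403494 to 35906780 counts. A gene reaching 3 counts in a library was at 0.0836 to 0.0987 CPM (counts scaled to a common library size), which covers counting error only. After the filter on low counts 15774 genes were tested. The design states 3 mice per group, but the sample labels do not tie each library to a single mouse, so the p-values measure the spread between these libraries.

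Tgfbr2 itself (ENSMUSG00000032440.13, minus strand of chromosome 9, 116084293 to 116175360 in GRCm38) stood at 187 ± 15.4 CPM in mutants and 191 ± 8.74 CPM in wt (SD, n = 3 each). Its log2 fold change was -0.03 with a standard error of 0.10, a 95% interval of -0.26 to 0.21 and an adjusted p of 0.996 by edgeR's quasi-likelihood test, and its sign turned positive without mutant replicate 1 (0.02) and without wt replicate 3 (0.01). The counts pool all exons of the gene, 8187 bases in 8 merged exons. In the floxed allele named in the design the loxP sites are known to flank exon 4, which in transcript Tgfbr2-201 spans 116109504 to 116110303 and is 800 bases long, 9.77% of that length. With even coverage, complete loss of this exon would lower the gene's count by 0.15 on the log2 scale (log2 change -0.15), which lies inside the interval. The gene-level count therefore does not check the genotype labels, and reads over the single exon, Cre and EGFP were not analysed here.

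Of the 15774 genes, 1 was higher in mutants and 0 were lower at an adjusted p under 0.05. The gene that rose was Ap1s1 (ENSMUSG00000004849.14, chromosome 5, 137034993 to 137046135), which encodes the small sigma subunit of the AP-1 adaptor complex that sorts cargo between the trans-Golgi network and endosomes. Ap1s1 was at 62.3 ± 8.48 CPM in mutants and 16.3 ± 1.27 CPM in wt (SD, n = 3 each), a 3.83-fold difference with a log2 fold change of 1.94 ± 0.16 (SE) and an adjusted p of 0.0034 by edgeR. All 3 mutant libraries lay above all 3 wt libraries. The mutants differ from wt in carrying the Cre transgene as well as in Tgfbr2, and whether the transgene lies on chromosome 5 near Ap1s1 was not analysed here. The fold change stayed between 1.87 and 2.05 on the log2 scale when each library was left out, but the adjusted p rose to 0.054 without mutant replicate 1, 0.083 without wt replicate 1 and 0.058 without wt replicate 3. At an unadjusted p under 0.05 there were 554 genes higher and 508 lower by edgeR, against 789 expected by chance in both directions together. The 3 libraries of each group did not overlap in 13.03% of the genes, against 10% by chance. DESeq2's Wald test called 81 genes higher and 74 lower, while limma-voom called 1 and 0. When only the genes with a mean of at least 10 CPM were tested, edgeR called 14 higher and 5 lower, and all 19 were also among the 155 DESeq2 calls.

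**Figure D1:**
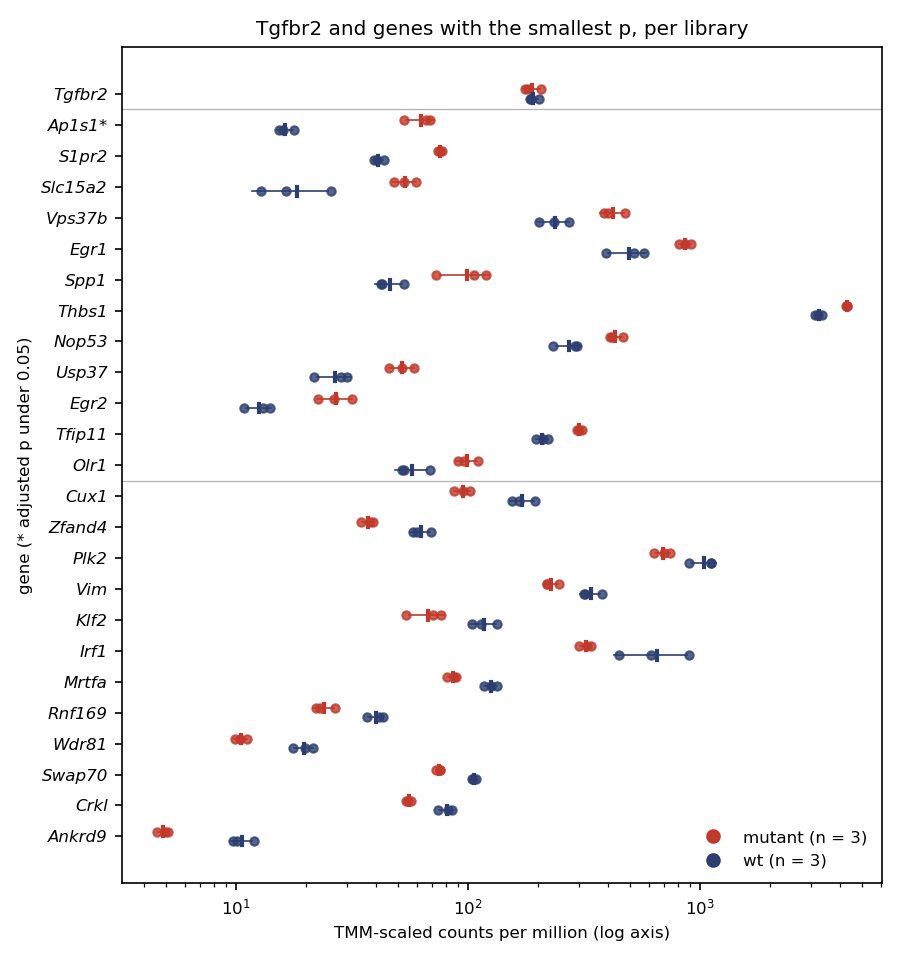
TMM-scaled CPM (log axis) of Tgfbr2, of the 12 genes with the smallest p higher in mutants and of the 12 lower in mutants, with points for the 3 mutant and 3 wt libraries, ticks at the group means and lines for ± 1 SD. Tgfbr2 overlaps between groups. The other 24 genes were chosen among those whose groups do not overlap, as in 13.03% of all tested genes against 10% by chance. Of these 24, Ap1s1 is the gene past an adjusted p of 0.05 by edgeR and the other 23 did not pass it there, while DESeq2 called all 24.

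The other 11 genes named on the higher side did not pass the adjusted threshold over all tested genes (adjusted p 0.165 to 0.263, edgeR), and their values are given for that reason without a call. S1pr2, a receptor for the lipid sphingosine 1-phosphate, was at 75.3 ± 1.29 CPM in mutants and 41.0 ± 2.08 in wt (SD, n = 3 each), a 1.84-fold ratio. Slc15a2, a transporter of short peptides, was at 53.4 ± 5.93 and 18.2 ± 6.59 CPM. The zinc finger transcription factor Egr1, an immediate early gene, was at 860 ± 53.4 and 493 ± 92.2 CPM, and Egr2 at 26.8 ± 4.58 and 12.6 ± 1.57 CPM. The secreted proteins Spp1 (osteopontin) and Thbs1 (thrombospondin 1, known to activate latent TGF-beta) were at 99.1 ± 23.9 against 45.8 ± 6.25 CPM and at 4275 ± 33.7 against 3232 ± 109 CPM. Olr1, the lectin-like receptor for oxidized LDL, was at 98.6 ± 10.2 and 57.4 ± 9.24 CPM. The ratios of the remaining genes were 1.78 for Vps37b of the ESCRT-I complex, 1.58 for the ribosome assembly factor Nop53, 1.95 for the deubiquitinase Usp37 and 1.44 for the splicing factor Tfip11. With genes under a mean of 10 CPM left out, 10 of these 11 had an adjusted p under 0.05, the exception being Thbs1 at 0.064.

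None of the 12 genes named on the lower side passed over all tested genes in edgeR (adjusted p 0.188 to 0.294), where 508 genes were lower at an unadjusted p under 0.05 and DESeq2 called 74. The homeodomain transcription factor Cux1 (chromosome 5, 136248135 to 136567490) was at 94.5 ± 7.52 CPM in mutants and 171 ± 19.9 in wt (SD, n = 3 each), a 1.81-fold ratio of wt over mutant. Irf1, a transcription factor induced by interferon, was at 321 ± 18.3 and 650 ± 223 CPM. Klf2, a transcription factor that restrains myeloid activation, was at 66.9 ± 11.6 and 117 ± 14.9 CPM, and the intermediate filament gene Vim at 228 ± 15.9 and 336 ± 34.0 CPM. Plk2, a polo-like kinase, was at 689 ± 54.2 and 1040 ± 129 CPM. Mrtfa, a coactivator of serum response factor, was at 85.7 ± 3.92 and 125 ± 8.03 CPM, Swap70, a regulator of actin and Rac, at 74.6 ± 1.86 and 106 ± 1.70 CPM, and the adaptor Crkl at 55.3 ± 1.40 and 80.6 ± 5.74 CPM. The ratios of wt over mutant were 1.68 for Zfand4, 1.68 for Rnf169, 1.88 for Wdr81 and 2.18 for Ankrd9. In the test restricted to a mean of at least 10 CPM, Cux1, Zfand4, Klf2 and Irf1 had adjusted p between 0.013 and 0.049. The libraries carry no strand information by design, and 3 of the 25 named genes overlap a gene with at least 10% of their own CPM: Vps37b with Hip1r, Usp37 with Cnot9 and Cux1 with Gm38082, so reads of these pairs may have been assigned to either.

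**Figure D2:**
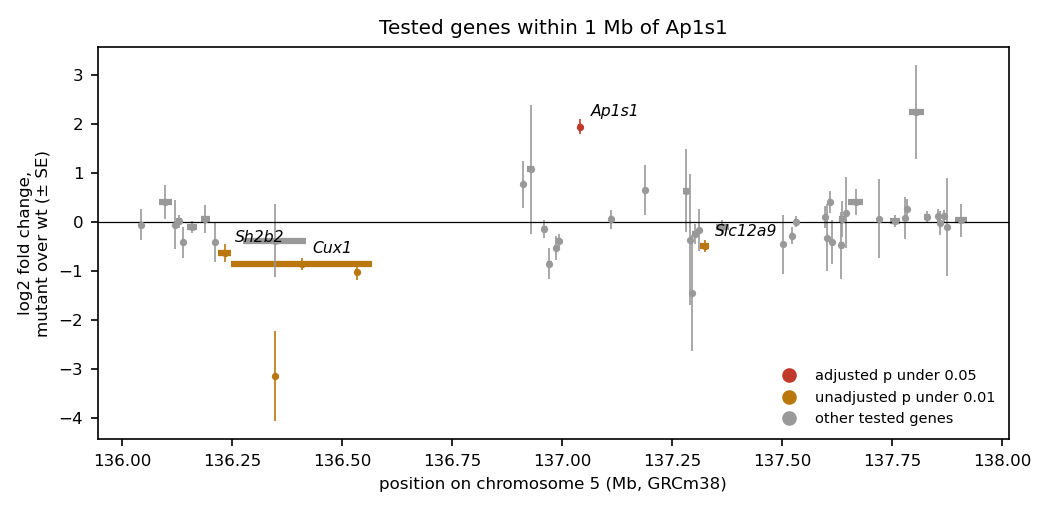
Log2 fold change of mutant over wt (± SE) of tested genes within 1 Mb of Ap1s1 by position on chromosome 5 (Mb, GRCm38), with horizontal bars for gene spans. Ap1s1 stands at 1.94, Cux1 at -0.86, Sh2b2 at -0.64 and Slc12a9 at -0.50, and of these Ap1s1 alone passed the adjusted threshold by edgeR, while DESeq2 also called Cux1 (adjusted p = 1.8e-07) and Slc12a9 (0.026).

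Camera called neither the TGF-beta-induced target genes nor the TGF-beta receptors and SMADs as shifted in one direction. Whether the listed genes respond to TGF-beta in lung neutrophils was not tested. Of 32 tested TGF-beta-induced target genes, 15 had a positive and 17 a negative log2 fold change, with a median of -0.01 and a camera adjusted p of 0.715. Over all genes 0 members passed by edgeR and by limma-voom, while DESeq2 called 2 higher and 1 lower, and edgeR had 6 higher and 2 lower at an unadjusted p under 0.05. Adjusted over the list alone 2 were higher and 1 was lower. Thbs1 is given above. Tgif1, a transcriptional repressor in the pathway, was at 352 ± 31.3 CPM in mutants and 254 ± 25.8 in wt (SD, n = 3 each). The ubiquitin ligase Smurf1, which targets SMADs and receptors, was at 7.19 ± 0.367 and 13.7 ± 2.84 CPM. The feedback inhibitor Smad7 was at 12.99 ± 2.00 and 12.6 ± 1.28 CPM and Skil, another feedback gene, at 203 ± 3.77 and 206 ± 32.2 CPM. Of 29 tested TGF-beta receptors and SMADs, 17 were positive and 12 negative, with a median of 0.11, an adjusted p of 0.715 and 0 members past the threshold adjusted over the list alone by edgeR. DESeq2 called 1 lower over all genes, where edgeR had 0, with 2 lower at an unadjusted p under 0.05. Bmpr2 in this list was at 57.1 ± 6.82 and 71.9 ± 4.59 CPM. By fry's test for change in either direction the target list had an adjusted p of 0.00084 and the receptor list of 0.0094. The same test had adjusted p under 0.05 for 10 of the 38 lists and does not compare a list with other genes.

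Among the 27 gene lists and 14 marker lists fixed before the data were examined, 38 had at least 5 tested members, and camera with a preset correlation of 0.01 between genes called 11 of them, 8 higher and 3 lower in mutants. With a correlation estimated from the data camera called 0, and fry's test of one direction called 0. Counts of members below are edgeR's unless DESeq2 is named, and limma-voom called 0 members of every list over all genes. Inflammatory genes were among the higher lists. Of 38 tested NF-kB feedback genes and inflammatory cytokines 28 were higher, with a median log2 fold change of 0.12 (camera adjusted p = 0.0092, and adjusted p = 0.662 with an estimated correlation). Over all genes 0 members passed by edgeR and 5 were higher by DESeq2, with 7 higher at an unadjusted p under 0.05 in edgeR. Adjusted over the list alone 6 were higher: Il1a at 92.7 ± 13.3 against 50.02 ± 11.6 CPM, Traf1 at 83.2 ± 2.95 against 57.8 ± 2.71 CPM, Il1r2, Nfkbie, Icam1 and Il1rn. Il1a encodes an agonist of the IL-1 receptor, whereas Il1r2 encodes a decoy receptor for IL-1, Il1rn an antagonist of the receptor and Nfkbie an inhibitor of NF-kB. The cytokine genes Il1b, at 13219 ± 2071 and 13749 ± 261 CPM, and Tnf, at 52.9 ± 14.8 and 39.3 ± 10.3 CPM, overlapped between groups. The list's call was lost without mutant replicate 2 (adjusted p = 0.076), mutant replicate 3 (0.079), wt replicate 1 (0.113) and wt replicate 3 (0.086). Markers of alveolar macrophages (median 0.64), epithelial cells (median 0.84), fibroblasts (0.44) and B and plasma cells (0.37) were higher in the same mutant libraries.

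Extracellular matrix and protease genes, phagocytosis and lysosome genes and lipid and prostaglandin metabolism genes were also shifted upwards. In the first, 21 of 28 members were higher, with a median of 0.18 (camera adjusted p = 0.0086, and adjusted p = 0.662 with an estimated correlation), and 7 passed adjusted over the list alone against 0 over all genes by edgeR, 4 by DESeq2 and 7 at an unadjusted p under 0.05. Spp1 and Thbs1, given above, lead this list. Its call was lost without mutant replicate 3 (adjusted p = 0.057) and without wt replicate 2 (0.086). In the second, 21 of 31 members were higher, with a median of 0.13 (camera adjusted p = 0.033, and adjusted p = 0.483 with an estimated correlation) and 0 members past the threshold adjusted over the list alone or over all genes by edgeR. DESeq2 called 1 higher over all genes, Lipa, and edgeR had 7 higher and 1 lower at an unadjusted p under 0.05. The lysosomal acid lipase gene Lipa was at 251 ± 36.1 CPM in mutants and 175 ± 24.5 in wt, and the cathepsin gene Ctsl at 107 ± 14.3 and 79.9 ± 6.47 CPM (SD, n = 3 each). This call was lost without mutant replicate 1 (adjusted p = 0.173), mutant replicate 3 (0.128), wt replicate 1 (0.080), wt replicate 2 (0.119) and wt replicate 3 (0.097), and with no filter on low counts (0.079). In the third, 24 of 34 members were higher, with a median of 0.11 (camera adjusted p = 0.036, and adjusted p = 0.483 with an estimated correlation). Olr1 was past the threshold adjusted over the list alone, against 0 members over all genes by edgeR, 1 by DESeq2 and 4 higher at an unadjusted p under 0.05. This call was lost without mutant replicate 1 (adjusted p = 0.197), mutant replicate 2 (0.092), mutant replicate 3 (0.056), wt replicate 1 (0.071), wt replicate 2 (0.064) and wt replicate 3 (0.118), and with no filter on low counts (0.053). Markers of alveolar macrophages, epithelial cells, fibroblasts and B and plasma cells, given below, were higher in the same mutant libraries.

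The lists shifted downwards were antigen presentation, cytosolic ribosomal proteins and mature and aged neutrophil genes. In the same mutant libraries markers of epithelial cells (median 0.84), alveolar macrophages (0.64), fibroblasts (0.44) and B and plasma cells (0.37) were higher. The medians of NK (-0.28) and dendritic cell markers (-0.31), which camera did not call, were below 0. Of 24 antigen presentation genes 19 were lower, with a median log2 fold change of -0.25 (camera adjusted p = 0.0098, and adjusted p = 0.662 with an estimated correlation) and 0 members past the threshold adjusted over the list alone or over all genes by edgeR, 0 by DESeq2, and 1 higher and 4 lower at an unadjusted p under 0.05. The class I genes H2-K1, at 2478 ± 149 CPM in mutants and 3452 ± 1106 in wt, and H2-Q7, at 110 ± 38.02 and 307 ± 235 CPM (SD, n = 3 each), had a wider spread among wt than among mutant libraries, and counts of class I genes are uncertain because near-identical copies can share reads. The costimulatory gene Cd83 went the other way, at 27.6 ± 8.21 and 16.3 ± 5.15 CPM. The call was lost without mutant replicate 1 (adjusted p = 0.110) and without wt replicate 1 (0.125). Of 68 cytosolic ribosomal protein genes 47 were lower, with a median of -0.15 (camera adjusted p = 0.0098, and adjusted p = 0.835 with an estimated correlation) and 0 members past the threshold on either count by edgeR, 0 by DESeq2 and 0 at an unadjusted p under 0.05. Rpl11 was at 10.8 ± 2.26 and 14.8 ± 1.27 CPM and Rplp2 at 3.08 ± 1.15 and 4.83 ± 1.27 CPM, and processed pseudogenes can take reads from this family. That call was lost without mutant replicate 1, where the median was 0.01 (adjusted p = 0.916), without mutant replicate 3 (0.157), without wt replicate 3 (0.276) and among genes with a mean of at least 10 CPM (0.363). Of 30 mature and aged neutrophil genes 22 were lower, with a median of -0.11 (camera adjusted p = 0.029, and adjusted p = 0.717 with an estimated correlation). Over all genes 0 members passed by edgeR, while DESeq2 called 3 lower and 1 higher, and edgeR had 4 lower and 1 higher at an unadjusted p under 0.05. Adjusted over the list alone 3 were lower and 1 was higher. The chemokine receptor gene Cxcr2 was at 2024 ± 99.2 and 2567 ± 80.8 CPM and Wfdc17 at 27.3 ± 9.86 and 53.1 ± 9.05 CPM. The call was lost without mutant replicate 1 (adjusted p = 0.173), mutant replicate 3 (0.414), wt replicate 1 (0.080) and wt replicate 2 (0.119), and with no filter on low counts (0.053).

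**Figure D3:**
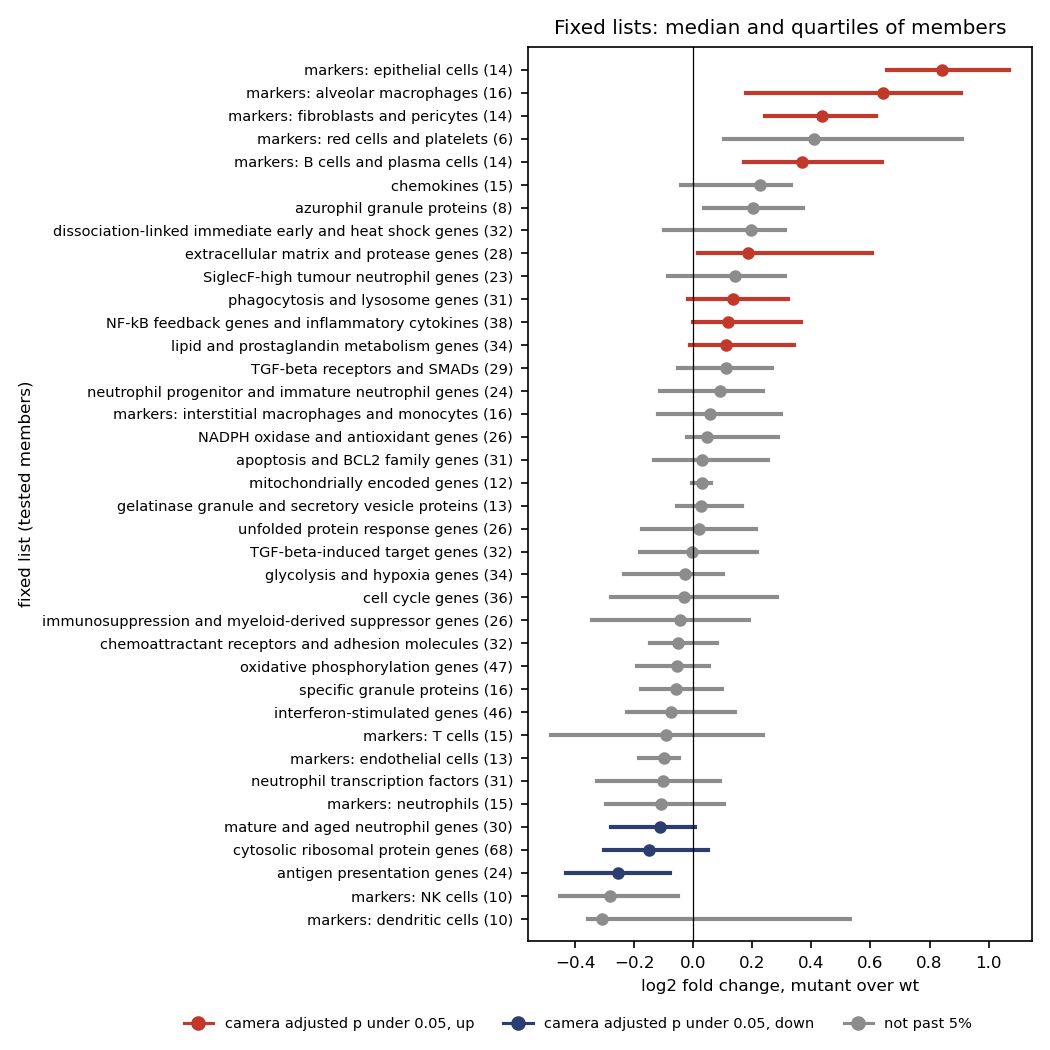
Median log2 fold change of mutant over wt (points) and quartiles (bars) over the tested members of the 38 lists with at least 5 tested members, coloured by camera's call with a preset correlation. Epithelial, alveolar macrophage and fibroblast markers have the highest medians (0.84, 0.64 and 0.44), and the TGF-beta-induced target genes sit at -0.01.

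The remaining neutrophil lists did not pass camera's threshold, and 0 of their members passed over all genes by edgeR. In the first 5 of them below, edgeR had at most 2 higher and 7 lower at an unadjusted p under 0.05, and DESeq2 called 1 azurophil gene higher, 1 specific granule gene lower and 2 transcription factors, 1 in each direction. Azurophil granule proteins had a median log2 fold change of 0.20 over 8 genes (camera adjusted p = 0.344). Adjusted over the list alone 1 was higher, the granule protease activator Ctsc at 82.6 ± 15.3 CPM in mutants and 52.1 ± 1.82 in wt. Prtn3 was low at 1.60 ± 2.22 and 0.404 ± 0.292 CPM (SD, n = 3 each). Its mutant mean rests on replicate 2 at 4.17 CPM, against 0.276 and 0.369 in mutant replicates 1 and 3. Specific granule proteins had a median of -0.06 over 16 genes (adjusted p = 0.504), with Chil3 higher at 631 ± 328 against 248 ± 79.5 CPM and Lrg1 lower at 924 ± 216 against 1365 ± 85.2 CPM when adjusted over the list alone. Gelatinase granule and secretory vesicle proteins had a median of 0.03 over 13 genes (adjusted p = 0.715), and 0 passed adjusted over the list alone. Ptafr, the receptor for platelet-activating factor, was at 839 ± 93.7 and 699 ± 80.6 CPM and Arg1 at 3.50 ± 4.93 and 0.717 ± 0.402 CPM. The Arg1 mutant mean rests on replicate 3 at 9.20 CPM, against 0.498 and 0.813 in mutant replicates 1 and 2. Progenitor and immature neutrophil genes had a median of 0.09 over 24 genes (adjusted p = 0.647), with 0 past the threshold adjusted over the list alone. Cebpe in this list was at 10.7 ± 3.53 and 6.70 ± 1.74 CPM. Neutrophil transcription factors had a median of -0.10 over 31 genes (adjusted p = 0.179). Adjusted over the list alone Irf1 was lower and Irf5 higher, at 177 ± 11.6 and 131 ± 5.93 CPM.

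In the next 6 lists edgeR had at most 7 higher and 6 lower at an unadjusted p under 0.05. DESeq2 called 1 interferon-stimulated gene lower, 1 chemoattractant receptor or adhesion gene in each direction, 4 dissociation-linked genes higher and 1 lower, 1 SiglecF-high gene higher, 1 immunosuppression gene higher and 2 lower, and 0 chemokines. Interferon-stimulated genes had a median of -0.07 over 46 genes (camera adjusted p = 0.295) and 0 past the threshold adjusted over the list alone. Gbp2, a guanylate-binding protein gene, was at 140 ± 23.2 CPM in mutants and 233 ± 51.8 in wt (SD, n = 3 each). Chemokines had a median of 0.22 over 15 genes (adjusted p = 0.409) and 0 past the threshold adjusted over the list alone, with Ccl3 at 48.9 ± 13.3 and 31.2 ± 10.5 CPM and Ccl4 at 39.5 ± 15.2 and 30.3 ± 5.71 CPM. Chemoattractant receptors and adhesion molecules had a median of -0.05 over 32 genes (adjusted p = 0.504) and 1 lower adjusted over the list alone, Cxcr2, while Icam1 was at 260 ± 44.5 and 183 ± 12.2 CPM. Dissociation-linked immediate early and heat shock genes, which respond to tissue digestion, had a median of 0.20 over 32 genes (adjusted p = 0.193), with 5 higher and 3 lower adjusted over the list alone, among them Egr1, Egr2 and Klf2. SiglecF-high tumour neutrophil genes had a median of 0.14 over 23 genes (adjusted p = 0.409), with Icam1 higher and Hif1a lower, at 108 ± 9.89 and 150 ± 20.5 CPM, when adjusted over the list alone. Immunosuppression and myeloid-derived suppressor genes had a median of -0.04 over 26 genes (adjusted p = 0.295). Adjusted over the list alone 1 was higher, Olr1, and 2 were lower, among them Wfdc17.

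Further lists of metabolism, stress and cell cycle did not pass either. Glycolysis and hypoxia genes had a median of -0.03 over 34 genes (camera adjusted p = 0.227), with Pfkfb3, which makes an activator of glycolysis, at 111 ± 7.68 CPM in mutants and 167 ± 28.9 in wt (SD, n = 3 each). Oxidative phosphorylation genes had a median of -0.06 over 47 genes (adjusted p = 0.227), with Ndufa1 at 1.91 ± 0.592 and 3.30 ± 0.428 CPM and Uqcrh at 12.5 ± 2.55 and 15.8 ± 1.19 CPM. NADPH oxidase and antioxidant genes had a median of 0.05 over 26 genes (adjusted p = 0.295), with Hmox1 at 75.4 ± 2.52 and 95.7 ± 2.95 CPM and the cystine transporter Slc7a11 at 730 ± 50.6 and 555 ± 106 CPM. Cell cycle genes had a median of -0.03 over 36 genes (adjusted p = 0.715), with E2f1 at 3.47 ± 1.68 and 1.15 ± 0.966 CPM and Mcm5 at 3.79 ± 2.19 and 1.47 ± 0.809 CPM. Unfolded protein response genes had a median of 0.02 over 26 genes (adjusted p = 0.715), with Atf4 at 121 ± 3.66 and 95.4 ± 4.37 CPM and Sdf2l1 at 6.14 ± 0.881 and 3.45 ± 1.03 CPM. Mitochondrially encoded genes had a median of 0.03 over 12 genes (adjusted p = 0.715), with mt-Rnr2 at 726 ± 108 and 662 ± 110 CPM and mt-Co1 at 853 ± 58.9 and 805 ± 151 CPM. In each of these 6 lists 0 genes passed adjusted over the list alone by edgeR, with at most 4 higher and 5 lower at an unadjusted p under 0.05, and DESeq2 called 1 glycolysis gene lower and 0 genes of the other 5. Apoptosis and BCL2 family genes had a median of 0.03 over 31 genes (adjusted p = 0.715). The survival gene Bcl2l1 was lower adjusted over the list alone, and by DESeq2 over all genes, at 104 ± 9.39 and 168 ± 37.4 CPM, and the BH3-only gene Pmaip1 was at 222 ± 43.4 and 167 ± 9.93 CPM. For the TGF-beta targets, specific granule proteins, chemoattractant receptors and cell cycle genes the median was negative and the mean positive, and camera's direction was up for the first of these and down for the others.

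Transcripts of other lung cell types were present in all libraries, and 4 of their marker lists were higher in mutants by camera with its preset correlation: epithelial cells, alveolar macrophages, fibroblasts and pericytes, and B and plasma cells. Of 14 epithelial markers 12 were higher, with a median log2 fold change of 0.84 (camera adjusted p = 0.00077, and adjusted p = 0.483 with an estimated correlation). The surfactant genes Sftpb, at 79.1 ± 13.8 CPM in mutants and 36.7 ± 13.8 in wt, and Sftpa1, at 167 ± 69.0 and 71.4 ± 27.5 CPM (SD, n = 3 each), lead the list, and 3 members passed adjusted over the list alone. The 2 lower members were the airway genes Scgb1a1, at 25.8 ± 9.52 and 30.01 ± 14.6 CPM, and Foxj1, at 0.254 ± 0.226 and 0.607 ± 0.275 CPM. Of 16 alveolar macrophage markers 15 were higher, with a median of 0.64 (camera adjusted p = 0.00032, and adjusted p = 0.483 with an estimated correlation). Ctsk, at 14.6 ± 4.45 and 5.56 ± 1.73 CPM, and Chil3, which is also counted among the specific granule proteins, passed adjusted over the list alone. Of 14 fibroblast and pericyte markers 12 were higher, with a median of 0.44 (camera adjusted p = 0.0064, and adjusted p = 0.662 with an estimated correlation), and 7 passed adjusted over the list alone. The collagen genes Col1a1 and Col3a1 were at 111 ± 30.4 against 69.5 ± 9.12 CPM and 155 ± 46.8 against 98.2 ± 11.3 CPM. Of 14 B and plasma cell markers 11 were higher, with a median of 0.37 (camera adjusted p = 0.013, and adjusted p = 0.717 with an estimated correlation) and 0 adjusted over the list alone. The B cell genes Cr2 and Ms4a1 were at 4.42 ± 0.951 against 1.60 ± 0.895 CPM and 10.6 ± 1.33 against 6.70 ± 3.23 CPM. The 3 lower members were the plasma cell gene Jchain, at 1.61 ± 1.54 and 3.78 ± 3.81 CPM, and the light chain genes Igkc, at 16.4 ± 4.27 and 17.3 ± 9.19 CPM, and Iglc2, at 1.41 ± 0.347 and 1.48 ± 0.908 CPM. The immunoglobulin A gene Igha, outside the list, was at 1.02 ± 1.25 and 13.7 ± 11.46 CPM. The epithelial and alveolar macrophage calls held whichever library was left out (highest adjusted p 0.026 and 0.024). The fibroblast call was lost without mutant replicate 3 (adjusted p = 0.079), and the B cell call without mutant replicate 2 (0.169), wt replicate 1 (0.328), wt replicate 2 (0.064) and among genes with a mean of at least 10 CPM (0.132). Over all genes 0 markers of any list passed by edgeR and 7 passed by DESeq2: 2 epithelial, 1 alveolar macrophage, 1 fibroblast and 3 neutrophil markers. At an unadjusted p under 0.05 edgeR had 7 epithelial, 7 alveolar macrophage, 8 fibroblast and 1 B cell marker higher.

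Markers of the other types were not shifted by camera. Endothelial markers had a median of -0.10 over 13 genes (adjusted p = 0.227), with Pecam1 at 241 ± 32.4 CPM in mutants and 288 ± 49.8 in wt and Ptprb at 277 ± 8.36 and 321 ± 57.4 CPM (SD, n = 3 each). NK cell markers had a median of -0.28 over 10 genes (adjusted p = 0.227), with Klrb1c at 3.30 ± 1.24 and 5.63 ± 2.19 CPM and Prf1 at 7.70 ± 1.94 and 10.6 ± 3.70 CPM. T cell markers had a median of -0.09 over 15 genes (adjusted p = 0.715), with Themis at 1.33 ± 0.254 and 0.465 ± 0.0796 CPM and Cd8b1 at 0.832 ± 0.435 and 2.23 ± 1.16 CPM. Dendritic cell markers had a median of -0.31 over 10 genes (adjusted p = 0.624), with Ccr7 at 21.9 ± 6.02 and 11.7 ± 3.77 CPM and Zbtb46 at 10.5 ± 2.12 and 13.5 ± 4.28 CPM. Interstitial macrophage and monocyte markers had a median of 0.06 over 16 genes (adjusted p = 0.726), with Nr4a1 at 5761 ± 288 and 4658 ± 920 CPM and Fn1 at 68.3 ± 21.3 and 50.4 ± 7.01 CPM. Red cell and platelet markers had a median of 0.41 over 6 genes (adjusted p = 0.175), with Hbb-bs at 1.08 ± 0.263 and 0.469 ± 0.313 CPM and Hba-a1 at 1.25 ± 0.594 and 0.601 ± 0.704 CPM. In these 6 lists 0 genes passed adjusted over the list alone by edgeR, with at most 1 gene higher and 0 lower at an unadjusted p under 0.05, and DESeq2 called 0. Neutrophil markers had a median of -0.11 over 15 genes (adjusted p = 0.227) and, adjusted over the list alone, 1 higher, the decoy receptor gene Il1r2 at 7173 ± 602 and 5165 ± 674 CPM, and 3 lower, among them Cxcr2. Eosinophil, mast cell and basophil, and sex-linked lists had fewer than 5 tested members and were not tested as lists. In them Siglecf was at 88.4 ± 20.6 and 80.1 ± 1.16 CPM, Ccr3 at 6.33 ± 2.36 and 5.76 ± 2.61, Cma1 at 0.0553 ± 0.0958 and 0.935 ± 0.709, Gata2 at 47.2 ± 6.74 and 61.4 ± 15.4, and Xist at 78.6 ± 5.75 and 72.2 ± 21.7 CPM, and 0 members passed adjusted over the list alone. Xist was present in all 6 libraries (47.9 to 89.7 CPM), and Y-linked genes had no counts except 6 counts of Uty in mutant replicate 1.

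Summed over each marker list, neutrophil markers stood at 48582 ± 5201 CPM in mutants and 48456 ± 1161 in wt (SD, n = 3 each). Alveolar macrophage markers summed to 972 ± 353 and 511 ± 116 CPM, epithelial markers to 752 ± 247 and 394 ± 162 CPM, fibroblast markers to 3496 ± 634 and 2668 ± 208 CPM and endothelial markers to 2795 ± 145 and 3074 ± 393 CPM. Chil3 was the largest single part of the alveolar macrophage sum, and most of the fibroblast sum was Gsn, at 2512 ± 412 and 1979 ± 190 CPM. The two-sided exact permutation p was 0.1 for alveolar macrophages and fibroblasts, 0.2 for epithelial and 0.3 for endothelial markers, and 0.1 is the smallest value that 3 against 3 libraries allow. Over the 14 sums the smallest Benjamini-Hochberg adjusted value of these exact tests was 0.56. The ratios of mutant to wt sums were 1.18 for interstitial macrophages and monocytes, 1.20 for B and plasma cells, 1.09 for dendritic cells, 0.918 for T cells, 0.826 for NK cells, 1.10 for eosinophils, 0.758 for mast cells and basophils and 1.26 for red cells and platelets, with exact p of 0.2 to 0.7. Single genes made up most of some of these sums. Nr4a1 was 5761 of 7107 CPM for interstitial macrophages and monocytes in mutants and 4658 of 6030 in wt. Ighm was 399 of 529 and 336 of 440 CPM for B and plasma cells. Siglecf was 88.4 of 95.8 and 80.1 of 86.9 CPM for eosinophils. Gata2 was 47.2 of 48.2 and 61.4 of 63.6 CPM for mast cells and basophils.

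**Figure D4:**
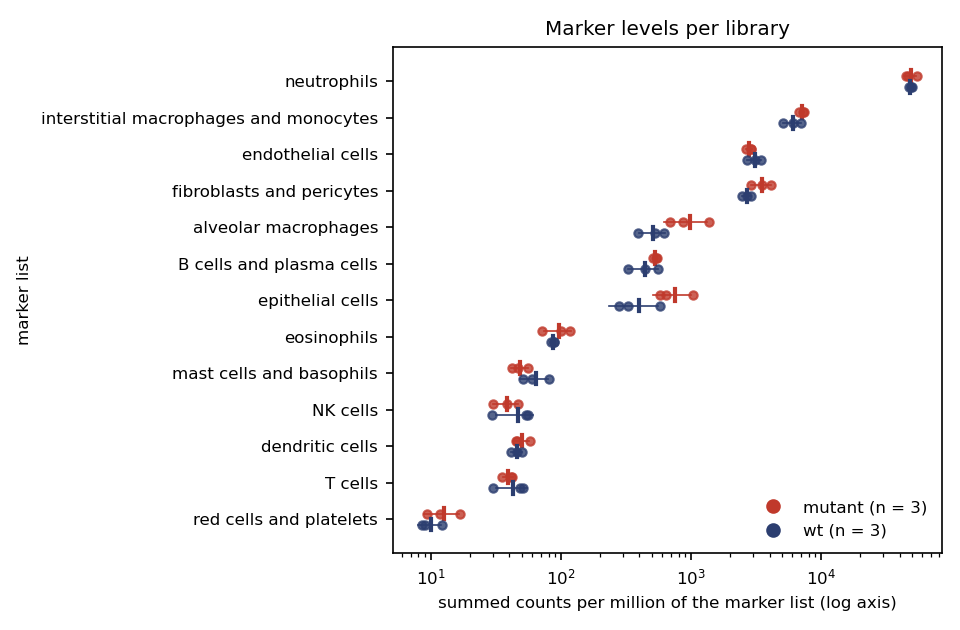
Summed CPM of each cell type's marker list (log axis), with points for the 3 mutant and 3 wt libraries, ticks at the group means and lines for ± 1 SD. Neutrophil markers average 48582 and 48456 CPM, while the 3 mutant libraries lie above the 3 wt libraries for alveolar macrophage markers.

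Correlations between libraries overlapped within and between genotypes. Pearson correlations of log2 CPM over the tested genes, which are not independent replicates, were 0.937 to 0.944 within groups and 0.934 to 0.941 between groups. On the 500 most variable genes the first principal component held 22.8% of the variance and the second 22.2%. Mutants lay at 6.39, 16.5 and 30.5 on the first component and wt libraries at -10.2, -32.0 and -11.1, so this component separated the groups, which was not tested. No pair of replicates differed by as little as sampling noise, with a chi-square per degree of freedom of 29.4 to 43.3 within groups and 31.0 to 54.9 between groups. The statistic is scaled to counting error only, and separate samples and PCR copies raise it in any case.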

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

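The edgeR fit with legacy = FALSE was chosen after seeing the data. Counts of 1 gene higher and 0 lower held with DESeq2's size factors, library totals alone, limma-voom with and without quality weights, edgeR's robust option, legacy = FALSE and an added log2 fold change of at least 1. DESeq2's Wald test gave 81 higher and 74 lower, no filter on low counts 41 and 29 over 26108 genes, and a mean of at least 10 CPM 14 and 5 over 6907 genes. The last tests fewer genes and also refits the dispersions on them, and the cause of all these differences was not tested. DESeq2 also called 11 genes in simulated data without a change, where edgeR called 0. All 19 genes of the mean CPM filter were among the 70 without a filter and the 155 of DESeq2. Leaving out each library gave 0 to 1 genes higher and 0 to 1 lower, the lower one being S100a8 without mutant replicate 2 (adjusted p = 0.026). Ap1s1 was called in 12 of 15 alternatives and in 3 of 6 fits that left out a library. Of the 24 genes named by rank, 24 passed by DESeq2, 17 with no filter, 15 with a mean of at least 10 CPM and 1 by limma-voom. The median log2 fold change of all tested genes was at most 0.0164 in size in every setting tried. Camera called 11 lists, and the count was 0 with an estimated correlation, 0 by fry, 11 with DESeq2's size factors, 9 with a mean of at least 10 CPM and 9 with no filter. Leaving out each library gave 4 to 10 lists, with 6 without mutant replicate 1, 4 without mutant replicate 3 and 6 without wt replicate 1. These fits have fewer samples. The ribosomal protein median ran from -0.38 to 0.0126 and was positive without mutant replicate 1. The first principal component held 22.1% of the variance over all tested genes. Without single libraries log2 fold changes ran from -0.0995 to 0.019 for Tgfbr2, -0.32 to 2.71 for Prtn3, -0.13 to 2.80 for Arg1, -0.0478 to 0.22 for mt-Co1, -0.0364 to 0.31 for Siglecf, -0.18 to 0.54 for Ccr3, -0.10 to 0.31 for Xist, -0.39 to 0.595 for Fabp4, -0.54 to 0.1994 for Scgb1a1, -0.0462 to 0.16 for Smad7, -0.0883 to 0.11 for Skil, -0.14 to 0.0676 for Il1b, -0.39 to 0.4058 for Igkc, -0.485 to 0.3779 for Iglc2 and -0.17 to 0.12 for Fos, so none of these has a settled direction. Fabp4 was at -0.0039 with DESeq2's size factors and at -0.0042 by its Wald test, and limma-voom without and with quality weights gave 0.0085 and 0.0358 for Igkc and 0.1477 and 0.1212 for Iglc2. Spike-in scaling was not run. At the depth of these libraries 32% of simulated 2-fold changes were recovered over all tested genes, against 78.9% at a mean of at least 10 CPM; other depths were not simulated.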

Other observations

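Of the tests in this part, those of the overlap and the interval around Ap1s1, of the TGF-beta target list, of the neutrophil share, of the library with the highest marker sums and of the 3 added lists were chosen after the result, or values of many of the genes in it, had been seen.

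Genes induced by interferon-gamma tended to be lower in mutants. The list was written after Irf1, Irgm2 and Gbp2 had been noticed among the genes with small p, and these 3 were left out. Of the 29 other members tested, 20 are also in the fixed lists, whose values had been seen. Of the 29, 26 had a negative log2 fold change, with a median of -0.44 (camera adjusted p = 0.00016 over the 3 added lists, and adjusted p = 0.246 with an estimated correlation). The immunity-related GTPase genes Igtp and Irgm1 were at 97.6 ± 1.05 CPM in mutants against 139 ± 47.3 in wt and at 65.6 ± 9.46 against 99.7 ± 38.8 (SD, n = 3 each), and the peptide transporter gene Tap1 at 188 ± 10.8 against 267 ± 104 CPM. The log2 fold changes of these genes were -0.51, -0.60 and -0.51 by edgeR. Without single libraries they ran from -0.72 to -0.22, -0.82 to -0.25 and -0.77 to -0.20. By edgeR 0 members passed over all genes or adjusted over the list alone, with 7 lower and 1 higher at an unadjusted p under 0.05, and DESeq2 called 1 higher and 0 lower. The list's call was lost without wt replicate 1 (adjusted p = 0.053). The interferon-stimulated list fixed before the data were examined had 27 of 46 members lower, a median of -0.07 and a camera adjusted p of 0.295. Markers of epithelial cells (median 0.84), alveolar macrophages (0.64), fibroblasts (0.44) and B and plasma cells (0.37) were higher in the same mutant libraries. The medians of NK (-0.28) and dendritic cell markers (-0.31), which camera did not call, were below 0.

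ERK-induced immediate early and feedback genes, listed after Egr1, Egr2, Egr3 and Dusp5 had been noticed and without them, had a positive log2 fold change in 21 of 29 members. Of the 29, 11 are also in the fixed lists, 9 of them in the dissociation-linked list, whose genes respond to tissue digestion and which had 21 of 32 members higher and a median of 0.20 (camera adjusted p = 0.193). Markers of epithelial cells (median 0.84), alveolar macrophages (0.64), fibroblasts (0.44) and B and plasma cells (0.37) were higher in the same libraries. The ERK list's median was 0.28 (camera adjusted p = 0.029, and adjusted p = 0.246 with an estimated correlation). Nr4a2 was at 42.8 ± 6.87 CPM in mutants and 23.5 ± 7.60 in wt (SD, n = 3 each), while Fos was at 5780 ± 1186 and 5907 ± 278 CPM. The call was lost without mutant replicate 3 (adjusted p = 0.137), wt replicate 1 (0.086) and wt replicate 3 (0.065). Glucocorticoid-induced genes, listed after Fkbp5 and Tsc22d3 had been noticed and without them, had a median of -0.05 over 27 members and a camera adjusted p of 0.139, which leaves open whether they moved together.

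Ap1s1, the gene called between the groups by edgeR in the main test, lies on chromosome 5 among 51 other tested genes within 1 Mb, of which Cux1 with 2 genes inside it, Sh2b2 (log2 fold change -0.64 ± 0.19, SE) and Slc12a9 (-0.50 ± 0.13) form 3 distinct loci with an unadjusted p under 0.01 by edgeR. Of these named genes DESeq2 also called Cux1 (adjusted p = 1.8e-07) and Slc12a9 (0.026). The count of other genes with reads that overlap Ap1s1 is 0, which argues against reads shared with an overlapping gene. A candidate explanation is an interval that the mutants carry and the wt mice do not, such as a transgene inserted near Ap1s1 or a linked haplotype: as many loci occurred in 3.33% of the 15722 windows around other tested genes, which would have met the first criterion. Among 6559 windows with a similar number of tested genes, a comparison added after that share was seen, it was 7.27%, and among 304 windows around other genes with small p 4.93%, so the shares fall on both sides of 5% and the interval stays open, with the position of the transgene not checked here. Loss of TGF-beta signalling cannot be told apart from it, because the transgene and the deletion come together and the TGF-beta target list (camera adjusted p = 0.715) does not separate them.

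Markers of alveolar macrophages, epithelial cells and fibroblasts were higher in mutants. A lower share of neutrophils in the mutant sorts would raise all other cell types alike if their mix stayed the same. The upper quartile of the endothelial log2 fold changes, -0.0481, lay below the lower quartiles of the epithelial (0.66), fibroblast (0.24) and alveolar macrophage markers (0.18). In these libraries the endothelial markers thus did not rise with the others. Quartiles over genes do not measure the spread between libraries, and the lists were set against each other after their shifts were seen. For the summed markers the exact permutation p was 0.2 for epithelial and 0.3 for endothelial cells, and the smallest adjusted value was 0.56. The comparison therefore cannot decide on a lower share with an unchanged mix. A lower share with a changed mix of other cells was not tested. Without mutant replicate 3, which had the highest sum of each of the 3 lists, 2 lists, alveolar macrophages and epithelial cells, stayed past 5% by camera with its preset correlation (adjusted p = 0.0018 and 0.0053), which argues against that library as their whole source, although with an estimated correlation and all libraries none of the 3 passed (0.483 for these and 0.662 for fibroblasts). The fibroblast median was 0.2941 without it against 0.44 with it and the call was lost (0.079), with summed markers of 2869 and 3481 CPM in mutants 1 and 2 and 2449 to 2862 in wt, so for that list it stays open. More alveolar RNA carried through the Ly6G gate, or a change in the neutrophils or in the lung, may remain. The alveolar macrophage gene Fabp4, at 3.58 ± 0.861 CPM in mutants and 3.57 ± 2.34 in wt (SD, n = 3 each), did not follow Chil3. Fabp4 is a single low gene without a settled direction, and 15 of the 16 tested markers of its list were higher, with a median of 0.64.

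Higher extracellular matrix, phagocytosis and lipid lists could come from marker genes of other lung cells within them. With members shared with such marker lists left out, 2 of the 3 lists stayed past 5% by camera, the matrix and lipid lists (adjusted p = 0.028 for both), and the phagocytosis list did not (0.092), with medians of 0.17 against 0.18 before for matrix, 0.12 against 0.13 for phagocytosis and 0.11 for lipid genes both times. With an estimated correlation none passed (adjusted p = 0.662 for the matrix list and 0.630 for the phagocytosis and lipid lists), and with all members the lipid call was lost whichever library was left out (0.056 to 0.197). Genes of those cells outside the marker lists remain in all 3, so this source cannot be told apart.

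The 6 libraries allow 10 splits, too few for a share under 0.05. The real split had 1 gene past 5% by edgeR and the highest other split 0, so 1 of the 10 splits gave as many. The real split had 11 lists past 5% by camera and the highest other split also 11, so 2 of the 10 splits gave as many.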
